A study of Homo sapiens with 10 samples.

How the data were processed

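Total RNA came from human CD4 T cells, which per the labels' protocols had been purified from blood mononuclear cells by negative selection and electroporated with an siRNA. Per the labels' protocols, libraries were made with a stranded poly(A) mRNA kit from at least 75 ng of RNA with a quality number above 8. The authors deposited a table of read counts per gene symbol and a table of FPKM values, with 1 column per library. Per the submitters' processing notes, HTSeq 0.9.1, DESeq2 1.16.1 and the hg38 build were used; the aligner, the annotation release and the strand setting are not given in the sources used here, so reads of overlapping and antisense genes may not be told apart. The deposited FPKM values were the deposited counts divided by 1 factor per gene and 1 per library, within 0.0163% over 3605 genes with 1000 or more counts in every library, and they entered only as an alternative.

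Groups and replicate numbers were taken from the sample titles, and all 10 libraries entered the comparison. Library pairs differed by a chi-square of 7.0 to 78.5 per degree of freedom, so no 2 libraries agreed within sampling noise. Counts were filtered with filterByExpr, scaled by TMM and tested with edgeR 4.0.16 (glmQLFit with robust dispersion, glmQLFTest, Benjamini-Hochberg over 17059 genes) in R 4.3.3, with no block as fixed before the data were examined. Standard errors are the absolute log2 fold change divided by the square root of F. CPM values are TMM-scaled, and log2 CPM used a prior count of 2. A count of 3 corresponds to 0.0587 to 0.202 CPM, counting error only.

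The same fit with the replicate number as a block was the alternative design chosen at the same time. Deviations from the group means correlated at 0.66 to 0.75 between libraries of the same number and at -0.37 to 0.09 between other numbers, so the numbers pair the samples by the data; the labels do not say what is shared. Other alternatives were DESeq2 1.42.0, limma 3.58.1 (voom, and trend on log2 FPKM with pseudocounts of 0.1 and 1), other scalings and filters, glmTreat at a fold of 1.2, and fits without each library or pair. On simulated counts for 17059 genes with 200 changed, the unblocked fit called 0 unchanged genes and the blocked fit 14.

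The rule for named genes took CD48 first, then up to 12 genes per direction past adjusted p 0.05 with a mean log2 CPM of at least 2, filled to 6 by the smallest unadjusted p where fewer passed, and up to 4 members per list past the threshold or otherwise 2 by the smallest p. Genes without a symbol, pseudogenes, receptor variable segments and sex-linked identity genes were not named, and 1 gene among the blocked calls is not reported here. The 51 lists, with 1020 genes of which 933 were tested, were run with camera at a preset correlation of 0.01, with an estimated correlation and with fry.

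Symbols were matched to GENCODE 29 on GRCh38 for position, GC content and sequence: 29679 matched by symbol and 908 by an older name, and 26245 did not match, mainly clone-named loci. A GC value existed for 78.8% of tested genes, too few for a check over all of them, so trends were computed on the 11402 genes with a mean log2 CPM of at least 2, of which 91.2% had one. The GC correction was a loess per library (span 0.4) used as an offset, run in the fit with the block. Exact permutation tests used scipy 1.17.1, and levels of genes that could reveal a donor's sex were left out.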

Results

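RNA from human CD4 T cells was sequenced in 10 libraries, 5 from each of 2 groups. In the control group the cells had been electroporated with a non-targeting siRNA (siNS) and given an isotype control antibody. In the other group they had received an siRNA against CD48 and a CD48 antibody. The cells were studied 4 days after electroporation. CD48 is a glycosylphosphatidylinositol-anchored receptor of the SLAM family that binds CD2 and CD244, and the series title places the comparison in a study of CD48, autophagy and cell death on restimulation. Knockdown and antibody always went together, so the comparison is of both at once. The libraries held 14839761 to 51094935 counted reads. The siNS libraries averaged 42959200 reads (SD 6943740, n = 5) and the siCD48 libraries 30780800 reads (SD 10182200, n = 5; exact permutation test, two-sided p = 0.0476; exact sign-flip test over pairs of the same replicate number, p = 0.125, 4 of 5 lower), and siCD48 replicate 4 was the shallowest. The labels give replicate numbers 1 to 5 in both groups without saying what a number stands for or whether the samples came from separate donors, so p-values measure the spread between these samples, which may be technical.

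CD48 was lower in all 5 siCD48 libraries than in any siNS library. The gene lies on chromosome 1 from 160678746 to 160711851 on the minus strand of GRCh38 (ENSG00000117091.9). It was at 206, 260, 229, 227 and 205 CPM (read counts scaled to library size) in siNS replicates 1 to 5 and at 122, 142, 166, 155 and 148 CPM in siCD48 replicates 1 to 5. The group means were 225 CPM (SD 22.5, n = 5) and 147 CPM (SD 16.3, n = 5), a log2 fold change of -0.62 (SE 0.09). The exact two-sided permutation test of log2 CPM gave p = 0.00794, and the exact sign-flip test over pairs p = 0.0625, each the smallest its design can give. Across 17059 tested genes, edgeR's quasi-likelihood test without a block gave CD48 an unadjusted p of 3.21e-05 and an adjusted p of 0.548. With the replicate number as a block the log2 fold change was -0.62 (SE 0.06) and edgeR's adjusted p was 0.000312.

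**Figure D1:**
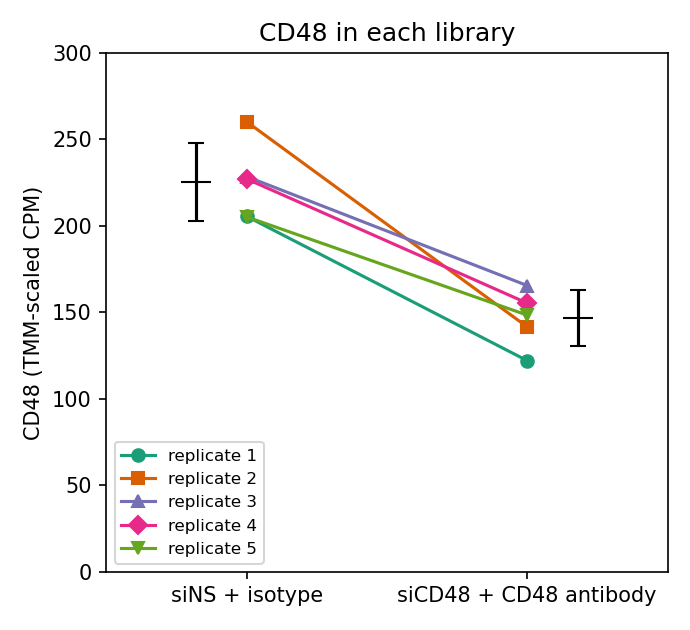
CD48 in TMM-scaled CPM (vertical axis) in each of the 10 libraries, with lines joining libraries of the same replicate number and black marks for the group mean and SD (n = 5). The siCD48 libraries lie between 122 and 166 CPM and the siNS libraries between 205 and 260 CPM.

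With the replicate number as a block, 9 genes were higher and 13 lower in siCD48 with antibody at an edgeR adjusted p under 0.05. Larger than the change of CD48 were those of USP41 (-3.68, SE 0.23) and GPR89B (0.89, SE 0.13), whose counts are uncertain, and of COL27A1 (0.70, SE 0.13). The lower genes included SLAMF7, a SLAM family receptor (log2 fold change -0.46, SE 0.07), the chemokine receptor CCR2 (-0.44, SE 0.08), the transcription factor MYB (-0.26, SE 0.045) and the zinc exporter SLC30A1 (-0.42, SE 0.06). The higher genes included the serine protease inhibitor SPINT2 (0.41, SE 0.05), the selenoprotein SEPN1 (0.32, SE 0.05) and the actin-bundling protein FSCN1 (0.28, SE 0.05). Each of these genes went the same way in 5 of 5 pairs. CCR2, FSCN1 and COL27A1 did not pass with a GC correction (edgeR adjusted p = 0.0712, 0.188 and 0.0535), with FSCN1 then at 0.18.

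Without the block no gene passed in edgeR. edgeR's quasi-likelihood test gave 0 genes higher and 0 lower, with 69 higher and 62 lower at an unadjusted p under 0.05, and DESeq2 gave 0 higher and 1 lower, which was CD48 (adjusted p = 0.00056). Same-numbered libraries deviated together, with correlations of 0.66 to 0.75 across genes, so the blocked values are given beside the unblocked ones. Leaving out replicate 1 moved the blocked counts to 549 higher and 431 lower, and leaving out replicate 4 moved them to 1 higher and 3 lower. Of the 22 genes, 22, 9, 12, 4 and 11 were called without pairs 1 to 5 in turn.

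The genes named by the rule fixed before the data were examined did not pass the unblocked test and are given as values. On the lower side after CD48 came the solute carrier SLC10A7, at 21.3 CPM (SD 2.57, n = 5) in siNS and 14.8 CPM (SD 1.27, n = 5) in siCD48 with a log2 fold change of -0.53 (SE 0.10), USP41 at -3.73 (SE 0.79), GPR89A at -0.36 (SE 0.10), TMEM65 at -0.26 (SE 0.07) and the TFIIA subunit GTF2A1 at -0.18 (SE 0.06). On the higher side were MAMLD1 at 0.39 (SE 0.13), GPR89B at 0.85 (SE 0.29), the prostacyclin receptor PTGIR at 0.59 (SE 0.20), the coronin CORO1B at 0.19 (SE 0.07), SEPN1 at 0.32 (SE 0.11) and the small heat shock protein HSPB1 at 0.28 (SE 0.10). Of these 12 genes, CD48, SLC10A7, USP41, GPR89A, TMEM65, GPR89B and SEPN1 passed with the block. SLAMF7, CCR2, MYB, SLC30A1, SLC27A2, FAM107B, SPATS2L, SPINT2, SEMA4C, COL27A1, DDT, VWCE and FSCN1 passed with the block and were chosen as blocked calls after their values were seen, except that SLAMF7 and MYB also came from the lists. Another of the 22 calls is a locus known only by a clone name.

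Counts of USP41, GPR89A, GPR89B and DDT are uncertain, because each shares at least 50% of its 31-base sequences with another gene. GPR89A and GPR89B together differed by a log2 value of -0.0522 (SD 0.0378, n = 5 pairs) while the GPR89A share of their sum was 82.4% (SD 6.15, n = 5) in siNS and 66.6% (SD 8.56, n = 5) in siCD48. USP41 was 6.34 to 8.74% of the sum of USP41 and USP18 in 4 siNS libraries, 0.873% in siNS replicate 2 and 0.439 to 0.844% in the siCD48 libraries.

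**Figure D2:**
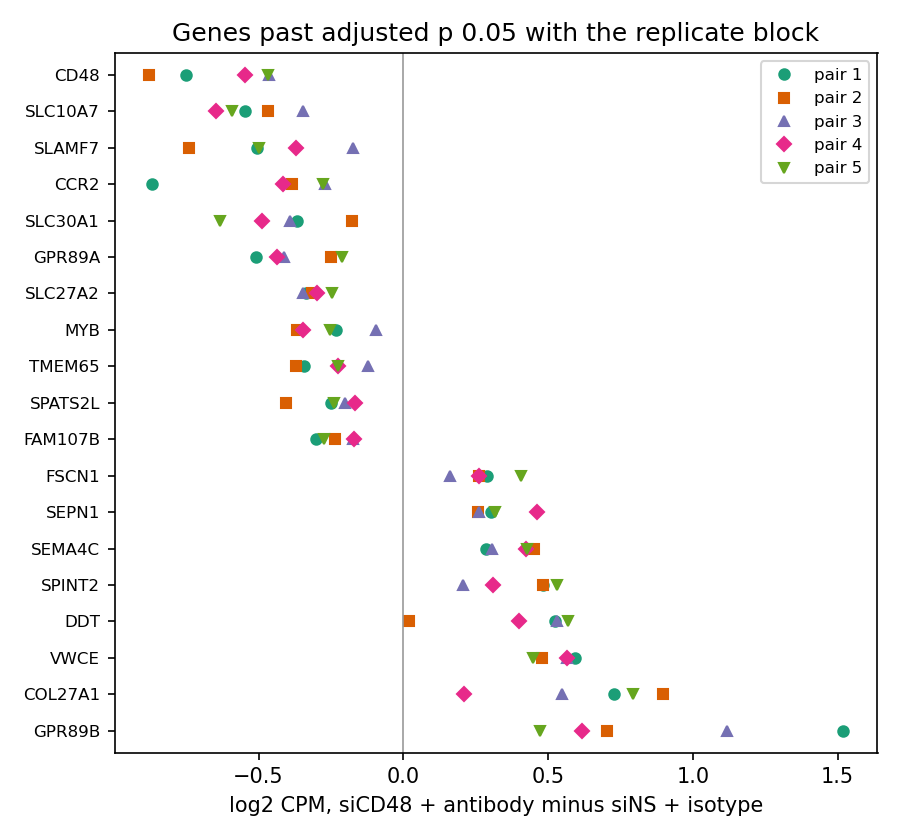
Difference in log2 CPM between the siCD48 and siNS libraries of the same replicate number (horizontal axis) for 19 of the 22 genes past an adjusted p of 0.05 with the replicate block, 1 symbol per pair. USP41, at -3.68, lies outside the range and is left out, as are the clone-named locus and 1 other gene; SLAMF7 and MYB lie below 0 in 5 of 5 pairs and SPINT2 above 0 in 5 of 5.

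Among 51 gene lists fixed before the data were examined, camera without the block called interferon-stimulated genes lower, mitochondrially encoded transcripts higher and unfolded protein response genes lower at a preset correlation. The interferon list had a median log2 fold change of -0.33 over 40 measured genes, and 39 of them were negative (adjusted p = 1.1e-11; adjusted p = 0.997 with an estimated correlation). IFIT2 was at 80.4 CPM in siNS and 58.3 in siCD48 (log2 fold change -0.47, SE 0.33) and IFI44 at 149 and 109.7 CPM (-0.45, SE 0.37), and neither passed alone. The 13 mitochondrial transcripts had a median of 0.37 and 13 of 13 were positive (adjusted p = 1.1e-11, or 0.997 with an estimated correlation). Among them were MT-ND5 at 0.38 (SE 0.15) and MT-CO1 at 0.32 (SE 0.13). That list had been written as a measure of library quality. Nuclear-encoded subunits of the respiratory chain and ATP synthase had 17 positive and 23 negative genes (median -0.00, camera, adjusted p = 0.993). In the unfolded protein list 20 of 23 genes were negative with a median of -0.07 (adjusted p = 0.000167; adjusted p = 0.63 with an estimated correlation), among them the chaperone HSPA5 at -0.16 (SE 0.06) and the transcription factor XBP1 at -0.13 (SE 0.06).

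Without the block fry called 0 lists. No member of the 3 lists passed over all genes tested or adjusted over the list alone without the block; with the block 4 unfolded protein genes passed adjusted over the list alone. Without the block the interferon call was lost without siCD48 replicate 1 (adjusted p = 0.354), while with the block the list passed in each of the 5 fits that left out 1 pair, and the unfolded protein call without the block was lost without siNS replicate 1 (adjusted p = 0.0828). The interferon medians of pairs 1 to 5 were -1.54, -0.69, -0.06, -0.10 and -0.07. The mitochondrial medians were -0.25, 0.31, 0.39, 0.76 and 0.48, and the share of all counts from mitochondrial transcripts was 2.23% (SD 0.437, n = 5) in siNS and 2.81% (SD 0.611, n = 5) in siCD48 (exact permutation test, two-sided p = 0.119; exact sign-flip test over pairs, p = 0.125).

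Camera with the replicate block called 10 lists. Besides the 3 above, NF-kB targets were called higher (20 of 24 positive, blocked median 0.07, adjusted p = 0.000652), Th1 genes lower (13 of 17 negative, blocked median -0.10, adjusted p = 0.031) and the SLAM family with its adaptors lower (11 of 14 negative, blocked median -0.09, adjusted p = 0.0361). G2/M genes (22 of 30 negative) and NRF2 targets (15 of 22 negative) were called lower, and glycolysis (19 of 24 positive) and ribosomal protein genes (42 of 50 positive) higher, at adjusted p = 0.0361, 0.0445, 0.0361 and 0.0361. With an estimated correlation 0 of these 10 lists passed, the lowest adjusted p being 0.553 for the unfolded protein list. Directional fry with the block called 0 lists, with its lowest adjusted p, 0.163, for the same list. With the GC correction G2/M genes (adjusted p = 0.258), glycolysis (adjusted p = 0.247) and the SLAM list (adjusted p = 0.0504) did not pass. In the 5 blocked fits without 1 pair, the interferon, mitochondrial, unfolded protein and NF-kB lists passed in 5, Th1 genes in 3, G2/M and ribosomal protein genes in 2, and the SLAM list, NRF2 targets and glycolysis in 1. Of 17 Th1 genes 8 were lower and 1 higher adjusted over the list alone, with IL18RAP at -0.47 (SE 0.11). TBX21, the Th1 transcription factor, differed by -0.14, 0.14, -0.22, 0.05 and 0.10 in pairs 1 to 5. IFNG differed by -0.30, 0.09, -0.25, -0.34 and -0.34. The Th1 median was 0.04 in pair 2 and below 0 in the other pairs. In the SLAM list 3 of 14 were lower adjusted over the list alone; SLAMF7 passed over all genes, and CD84 was at -0.23 (SE 0.05).

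**Figure D3:**
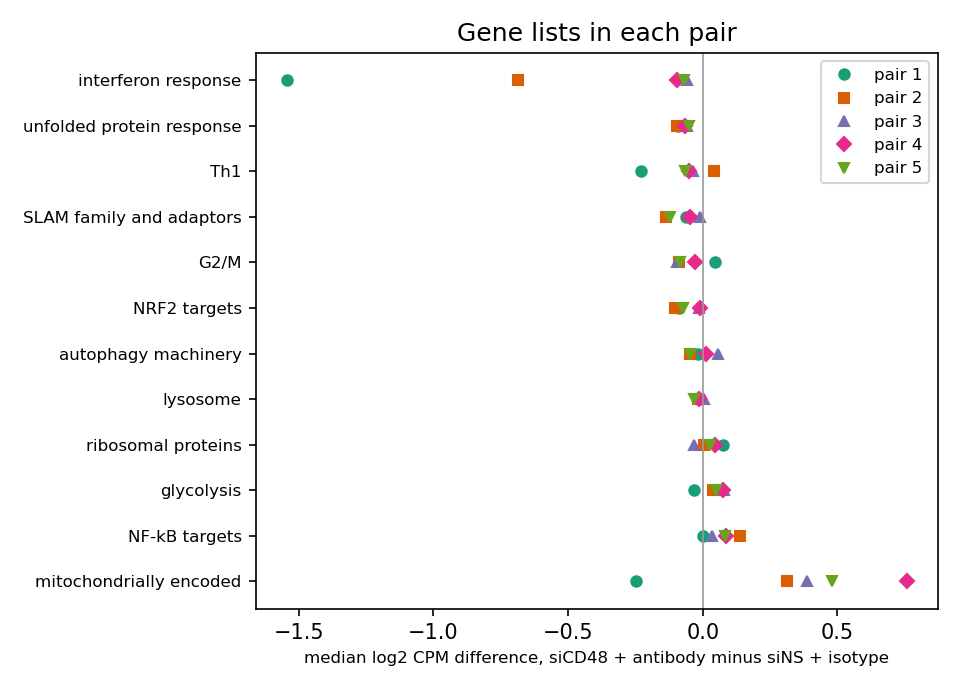
Median difference in log2 CPM between the siCD48 and siNS libraries of the same replicate number (horizontal axis) over the measured genes of 12 lists, 1 symbol per pair. The interferon medians run from -1.54 in pair 1 to -0.06 in pair 3, and the mitochondrial medians are above 0 in 4 of 5 pairs.

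Genes of the process in the series title showed no shift as a list. Of 43 autophagy machinery genes, 21 had a positive and 22 a negative value without the block, with a median of -0.00 and pair medians between -0.05 and 0.06 (camera, adjusted p = 0.993; 0.84 with the block). Members with the smallest p were ATG2A at 0.16 (SE 0.09) and ATG4A at -0.14 (SE 0.09). Autophagy receptors (median -0.02 over 19 genes), lysosome genes (-0.01 over 45), the death receptor pathway (-0.04 over 25), the BCL2 family (-0.03 over 18) and T cell receptor signalling (-0.00 over 39) each had an adjusted p of 0.993. The mixed fry test with the block, which asks whether members change in either direction, passed for 15 lists, among them the BCL2 family (adjusted p = 0.00074), the death receptor pathway (adjusted p = 0.00879), lysosome genes and T cell receptor signalling (adjusted p = 0.0395 for both), but not for autophagy machinery (adjusted p = 0.392) or receptors (adjusted p = 0.248). Without the block that test passed for 0 of 51 lists. The mixed test was not run with the GC correction, so the GC trend described below was not removed from its results. Simulated data give rates for single genes, not for lists. The changed genes had a mean log2 CPM over 2 and the same fold in every pair. Genes were drawn independently and without the GC trend, so the rates may not hold for these data. Without the block edgeR's test recovered 0% of genes changed 1.2-fold, 48% of those changed 1.5-fold and 80% of those changed 2-fold. With the block it recovered 68%, 100% and 98%.

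Across the 48 lists past no threshold without the block, medians lay between -0.13 and 0.20 and adjusted p between 0.114 and 0.993. The 8 lists of other blood cell types stayed at adjusted p from 0.195 to 0.854 with the block. They held only 3 to 8 measured genes each, so they say little about other cells. CD8A was at 1.39 CPM (SD 0.120, n = 5) in siNS and 1.54 CPM (SD 0.367, n = 5) in siCD48. The monocyte gene LYZ was at 0.788 and 0.529 CPM, lower in 5 of 5 pairs. The immunoglobulin gene IGHM was lower in the blocked fit with the GC correction (log2 fold change -0.33, SE 0.05, edgeR adjusted p = 0.00366).

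The differences within pairs followed the GC content of the transcript. Across 10393 genes with a mean log2 CPM of at least 2 and a GC value, which are not independent replicates, Spearman's rho between the difference and GC content was -0.28 in pair 1 and 0.50, 0.43, 0.35 and 0.61 in pairs 2 to 5. With a GC correction in the blocked fit, an alternative added after the data were seen, 4 genes were higher and 13 lower, 13 of them among the 22, and CD48 was at -0.59 (SE 0.06, edgeR adjusted p = 0.00147). Of those that did not pass after it, FSCN1 was at 0.18 (SE 0.05), TMEM65 at -0.20 (SE 0.05), CCR2 at -0.40 (SE 0.08) and DDT at 0.36 (SE 0.09), against 0.28, -0.26, -0.44 and 0.41 before. SEMA4C at 0.31, COL27A1 at 0.62, VWCE at 0.44 and FAM107B at -0.19, against 0.38, 0.70, 0.53 and -0.23 before, did not pass either, while SLAMF7, MYB, SLC30A1, SPINT2 and SEPN1 did. Genes outside the 22 that passed only after the correction were PTGIR (0.51), higher, and IGHM (-0.33), KLF2 (-0.54) and RRBP1 (-0.24), lower.

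**Figure D4:**
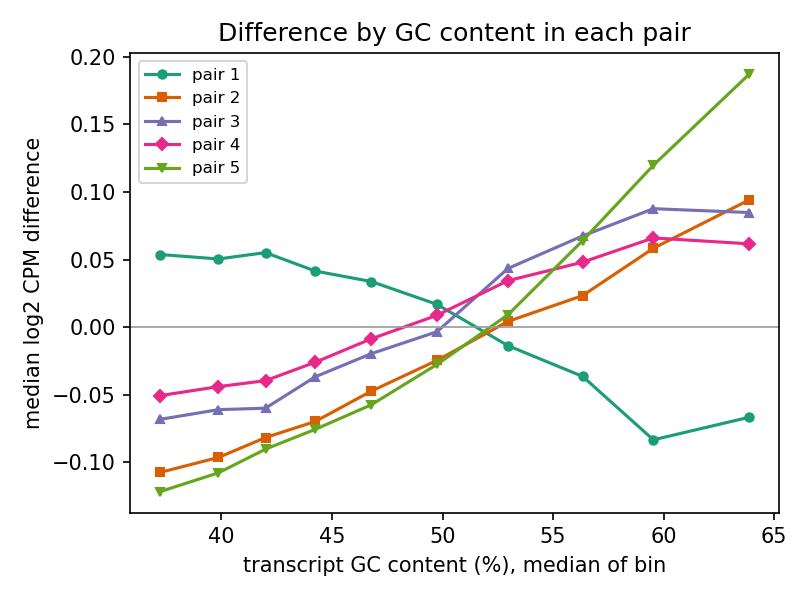
Median difference in log2 CPM (vertical axis) in 10 bins of equal size of 10393 genes ordered by transcript GC content in percent (horizontal axis), 1 line per pair of the same replicate number. The line of pair 1 falls with GC content and those of pairs 2 to 5 rise.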

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

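All tests of explanations here were chosen after the results were seen, except thinning for the interferon list and the GC correction without pair 1. In groups of 5, a library was picked out when its gap to the next exceeded 0.71 of the group's range, which chance does in about 5% of groups; 4 of 78 groups were picked out. MAMLD1 was at 3.53 CPM in siNS replicate 3 against 4.03 to 4.22 in the others. COL27A1 was at 3.63 CPM in siNS replicate 5 against 1.08 to 1.66. VWCE was at 4.90 CPM in siNS replicate 5 against 2.38 to 2.98, and at 6.70 CPM in siCD48 replicate 5 against 3.60 to 4.44.

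Near-identical copies were seen among the blocked calls, and a count made afterwards gave 4 of 21 against 707 of 13415 other tested genes (Fisher's exact p = 0.0227). With GPR89A and GPR89B, copies of each other, counted once it was 3 of 20 (Fisher's exact p = 0.0858), so over-representation stays undecided. The sum of GPR89A and GPR89B differed by a log2 value of -0.0522 (SD 0.0378, n = 5 pairs) and that of DDT and DDTL by 0.0799 (SD 0.0747, n = 5 pairs). A shift of reads from one gene to the other is therefore a candidate explanation for both pairs of genes. DDTL shares only 17.8% of its 31-base sequences with another gene. It also overlaps DDT on chromosome 22, DDTL on the plus strand (23966901 to 23972532) and DDT on the minus strand (23971365 to 23979828). The strand setting is not known, and whether reads of the overlap were assigned differently was not tested. The DDTL share of its sum was 24.1 to 28.0% in 4 siNS libraries, 0 of 890 counts in siNS replicate 2, which allows up to 0.337%, and 0.299 to 2.63% in siCD48, lower in 4 of 5 pairs; in pair 2 DDT differed by 0.02. For USP41 the sum with USP18 could not decide, since USP41 was on average 6.09% of it in siNS. For both USP41 and DDTL, siNS replicate 2 lay near the siCD48 libraries and far below the other 4 siNS libraries. The DDTL share therefore does not follow the groups in every library. The USP41 share was lower in every siCD48 library than in any siNS library (exact permutation test, two-sided p = 0.00794). For siNS replicate 2 the margin was small, 0.873% against at most 0.844% in siCD48. What siNS replicate 2 has in common with the siCD48 libraries was not tested. Whether the groups differ in a transcript form that changes read assignment was not tested either.

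The fall of the interferon list was carried by pairs 1 and 2. The tables argue against GC content as its cause, since 97.8% of the list median was left after the GC correction, and against depth, since 98.3% was left after thinning all libraries to the smallest total. An effect of the CD48 siRNA with antibody stays open, because 5 pair medians below 0 give an exact two-sided sign-flip p of 0.0625, the smallest that 5 pairs can give. The 2 siRNAs are different molecules and go with the groups, so their own effect on interferon genes cannot be told apart from that of CD48.

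Leaving out pair 1 raised the blocked calls to 980. These calls rest on pairs 2 to 5, and in pair 1 32.2% of 979 had the same direction, which argues against one effect of about the same size in every pair. On genes with a GC value the fit without pair 1 gave 1268 calls before and 244 after the GC correction, 19.2% as many, and 154 of 914 calls with a GC value passed after it, so a GC-dependent difference between libraries is a candidate explanation for most of them. Among 914 of the 980 with a GC value the median absolute log2 fold change was 0.18 before and 0.10 after the correction with a median SE of 0.04 both times, so the calls ended because the fold shrank. A biological difference that follows GC content would be removed as well, and remains open.

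Other splits of the libraries bear on the counts. Without the block the real count was 0 genes, which any split reaches (100 of 100, highest other 17), so this comparison says nothing about chance. For the lists without the block 95 of 100 splits gave at least the real 3, the highest other 25, so chance cannot be excluded. Splits that keep pairs together differ by what the pairs share: those parting 1 pair gave 8 to 25 lists, and of the 12 that part all 5 pairs, as the real one does, 7 gave at least 3 and the highest other 5. With the block, 16 splits exchange libraries within pairs, too few for a share under 0.05. The real split gave 22 genes, which 2 of the 16 reached with the real one counted, the other giving 483 and the remaining ones at most 2. That other split sets pair 1 against the other 4, and the cause of its count was not tested. The real split gave 10 lists, which 1 of the 16 reached, itself, and the highest other gave 8.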

How the results depend on the processing

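Alternatives with a GC correction, with thinning, on genes with a GC value, with limma voom and the block, and lists without single pairs were chosen after seeing the data; the cause of the changes was not tested except where the construction shows it. The CD48 log2 fold change stayed negative under every setting run. It passed the threshold with DESeq2 (-0.62), the replicate block (-0.62), the block with DESeq2 (-0.62), GC correction (-0.59), genes with a GC value (-0.62), thinning (-0.59) or limma voom (-0.62), and in the blocked fits without pairs 1 to 5 in turn (-0.59, -0.56, -0.66, -0.64 and -0.66; with GC correction -0.55, -0.53, -0.62, -0.60 and -0.63; on genes with a GC value without pair 1, -0.58); without 1 library it ran from -0.67 to -0.56. Without the block no setting but DESeq2 (0 higher, 1 lower) called a gene. The block gave 9 higher and 13 lower genes, with DESeq2 18 and 29, with GC correction 4 and 13, on genes with a GC value 8 and 13, after thinning 6 and 9, and with limma voom 7 and 12. Blocked fits without pairs 1 to 5 in turn gave 549, 4, 5, 1 and 6 higher and 431, 8, 14, 3 and 9 lower genes, with GC correction 126, 2, 2, 1 and 1 higher and 118, 8, 14, 5 and 9 lower, and without pair 1 on genes with a GC value 793 and 475; fits without 1 library gave 0. Lists past the threshold numbered 3, 0 with an estimated correlation, 0 with fry, 10 with the block, 10 with the block and thinning and 7 with the block and GC correction; they ran from 3 to 8 without 1 library and from 4 to 7 without 1 pair. Of 26 named genes, 21 passed with the block, and 13 of the 25 with a GC value passed with GC correction; the clone-named locus has no such value. None reversed direction in the settings run for it. With every library thinned to the smallest total, 13 of the 22 blocked calls remained; on simulated data, 48% of genes changed 1.5-fold were recovered without the block and 100% with it.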

Other observations

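The test of seed matches below was chosen after the result was seen. CCR2, among the genes lower with the block, lies on chromosome 3 (46353734 to 46360928 on GRCh38). CCR1 (46201709 to 46208396) and CXCR6 (45940933 to 45948353) lie near it. CCR8 (39329706 to 39333511) is on the same chromosome but much farther away. In the blocked edgeR fit CCR1 was at -0.65 (SE 0.18, adjusted p = 0.356) and CXCR6 at -0.27 (SE 0.06, adjusted p = 0.108), each lower in 5 of 5 pairs without passing, while CCR8 was at 0.51 (SE 0.12, adjusted p = 0.131) and higher in 5 of 5. The Th2 cytokine IL13 was at 0.40 (SE 0.08, adjusted p = 0.111), higher in 5 of 5 pairs. The Th2 gene IL1RL1 went the other way in 5 of 5 pairs, by -1.04 to -0.14. The Th2 list had 8 positive and 7 negative genes with the block and was not called in one direction (camera with the block, adjusted p = 0.682). Its members did change in either direction by the mixed fry test with the block (adjusted p = 4.58e-05). With the block 4 of them were higher and 1 lower adjusted over the list alone. The mixed test passed for 0 lists without the block and was not run with the GC correction. SLAMF7 lies at 160739057 to 160754821 on chromosome 1, beside CD48. Of the SLAM genes around it CD84 was at -0.23 and SLAMF6 at -0.16, each lower in 5 of 5 pairs without passing. LY9 was at -0.19 and lower in 4 of 5, and SLAMF1 at -0.05 and CD244 at -0.11 were each lower in 3 of 5. SLAMF8, farther away at 159826750 to 159837249, differed by 0.53, 0.47, 0.31, 0.03 and -0.07 in pairs 1 to 5. The list of other genes near the locus had a median of 0.00 over 14 genes.

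A hypothesis was that the CD48 siRNA lowers other transcripts through short seed matches in their 3' untranslated regions. Over 1052 7-base sequences of the CD48 transcript and 9755 genes, the lowest statistic belonged to AACGAGG (z = -2.91, 175 genes with a match), with a family-wise permutation p of 0.447. The test therefore gave no evidence for seed matches, and effects on few genes may have been missed. It covered only sequences as they stand in the CD48 transcript. Those of the opposite strand and of the control siRNA were not searched, and the many candidates make a single seed hard to find.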
